A study of Zea mays with 2 samples.

How the data were processed

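Transcript abundance was measured by RNA sequencing in endosperm, the starch- and protein-storing tissue of the maize kernel, taken 15 days after pollination from wild-type kernels (WT) and from the rea1 mutant. Total RNA was extracted, treated with DNase I and made into Illumina libraries, per the labels' protocols. The series' design text speaks of triplicates, but the data analysed here hold 1 file per genotype with a single value per locus. Whether each file is 1 library, a pool or a mean of 3 is not given in the sources used here, and each file is called a library below. Each genotype therefore has 1 sample, no spread between replicates could be estimated, and no p-value is given.

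The authors deposited FPKM values, fragments per kilobase of transcript scaled to the mapped fragments of each library, named as such per the file headers. The submitters' processing notes name Bowtie 0.12.2. The program that estimated FPKM, the genome build, the annotation and any filter are not given in the sources used here. Each file lists the same 12140 rows in the same order, identified only by chromosome, start and end. Of these, 833 rows shared 403 positions. Each row is counted as a locus below unless positions are said to be summed. No gene name or identifier accompanies a locus, and the gene table at hand belongs to an assembly named Zm-B73-REFERENCE-NAM-5.0 that could not be matched to unlabelled coordinates, so no locus was named. The gene lists fixed before the data were examined, the level of the mutated gene and the alternatives built on storage protein genes were therefore not analysed here. The difference between end and start was divisible by 3 for 4825 loci (39.7%) and left a remainder of 2 for 3651 (30.1%). Coding lengths are multiples of 3, so starts were read as counting from 0 and are printed 1 higher than deposited, counting from 1. Coordinates belong to the unstated build of the files.

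The files hold no read counts. In loci of 1000 to 3000 bp whose span is a multiple of 3, the lowest 2% of values above 0 lay below 0.0866 FPKM times kilobases in rea1 and below 0.108 in WT, a ratio of 1.25. If these lowest values stand for 1 fragment, 1 FPKM over 1 kb corresponds to about 11.6 fragments in rea1 and 9.22 in WT, and 10 FPKM to about 116 and 92.2 fragments. Introns make the span longer than the transcript, so these numbers are rough. A 2-fold difference near 1 FPKM then lies near counting error, and one above 10 FPKM in a locus of 1 kb lies well outside it. In loci of 200 to 300 bp whose span is a multiple of 3, the lowest 2% of values above 0 reached 1.20 FPKM in rea1 and 2.26 in WT. Nearly all such loci therefore passed 1 FPKM once they had any value.

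From the FPKM values the log2 ratio of rea1 over WT was computed as log2(FPKM + 1) in rea1 minus log2(FPKM + 1) in WT. The pseudocount of 1 understates differences of low loci. Loci were counted as higher or lower at 2-fold or more among those whose higher value was at least 1 FPKM. Values were used as deposited, with no further scaling. Shares of the summed FPKM were taken over the listed loci. Medians over loci carry a 95% interval from the binomial order statistics, and shares of loci carry a 95% Wilson interval. Both concern the loci of these libraries only, since loci are not replicates. Both treat loci as independent, which neighbouring loci and rows of one position may not be. Span means the genomic distance from start to end, introns included.

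The rule for single loci, fixed before the data were examined, was the 2 highest and the 2 lowest log2 ratios among loci reaching 10 FPKM, for the case that no names were at hand. The limit of 500 bp on span, the expression classes, the joining of loci at a mean of 1000 FPKM or more within 250 kb into regions, the comparison of chromosomes and all other loci given by position were chosen after the values were seen. Alternatives tried were pseudocounts of 0.1 and 10, other filters on low values, thresholds of 1.5-fold and 4-fold, scaling to a median ratio of 0 among loci at 10 FPKM or more in both libraries, scaling by a trimmed mean of log ratios (30% of ratios and 5% of levels trimmed on each side), and rescaling without the 100 most abundant loci. The calling and scaling steps were run on simulated data built from the WT values of all 12140 loci. The changed loci were drawn from those at 10 FPKM or more in WT, and the added noise was small. All of them were called, 100 of 100 raised 4-fold and 100 of 100 lowered 4-fold. An added log2 shift of 0.5 was recovered as 0.5 by the trimmed mean and 0.49 by the median. Such changes pass the 2-fold threshold by design, and a uniform shift carries into the trimmed mean by arithmetic. The run therefore checks the code only and gives no rate of missed or false calls in real libraries. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.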

Results

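Endosperm transcriptomes of the rea1 mutant and of wild type (WT) were compared 15 days after pollination, with 1 library per genotype. The comparison asked which transcripts differ in the mutant. The study is known to have traced rea1 to a homologue of midasin, an AAA-ATPase that acts in assembly of the large ribosomal subunit, but its level was not analysed here because the loci carry no gene names. Of 12140 loci, 12127 lay on the 10 chromosomes and 13 on scaffolds. In total 3807 loci were listed at 0 in rea1 and 3894 in WT, and 2727 of these were listed at 0 in both. The summed FPKM was 452816 in rea1 and 456377 in WT. Across the 10926 loci with a span of 500 bp or more, log2(FPKM + 1) of the libraries had a Pearson correlation of 0.95, which describes loci and not replicates.

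Many of the most abundant loci, mainly those clustered in 4 short regions, were far lower in the rea1 library. Of 19 loci with a span of at least 500 bp and a mean of 1000 FPKM or more, 11 were at least 2-fold lower in rea1, none was 2-fold higher, and 8 lay within 2-fold. Their median log2 ratio was -1.44 (95% interval -1.90 to -0.18). Many of the 19 loci are neighbours and some are rows of one position, so this interval may be too narrow. These 19 loci held 75.2% of the summed FPKM of loci of this span in WT and 43.2% in rea1. Over all spans, with the 500 bp limit lifted, loci at a mean of 1000 FPKM or more held 76.7% in WT and 70.2% in rea1, with a single 167 bp locus of chromosome 8 at 141583 FPKM in rea1. Of the 19, 11 lay in 4 short regions on chromosomes 1, 4 and 7, and these regions alone held 71.4% of the summed FPKM of loci of 500 bp or more in WT and 36.3% in rea1. Of the sum over all spans they held 60.1% in WT and 17.8% in rea1. The 167 bp locus, listed at 0 in WT, alone made up 31.3% of that rea1 sum. Part of the lower rea1 share over all spans therefore comes from this single locus.

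The region with the highest summed FPKM spanned positions 18755936 to 18878182 of chromosome 7 and held 7 loci, of which 6 reached 1 FPKM. Its summed FPKM was 195422 in WT and 56859 in rea1, a 3.44-fold difference. All 6 loci were lower in rea1, 5 of them by 2-fold or more, and all 6 were between 722 and 726 bp long. The most abundant locus in WT, at 18865424 to 18866146, had 144212 FPKM in WT and 44053 in rea1, 3.27-fold lower. Its neighbour at 18877460 to 18878182 had 35152 FPKM in WT and 11508 in rea1. Between them, at 18867732 to 18868453, FPKM was 1505 in WT and 212 in rea1, a 7.10-fold difference. At 18755936 to 18756661 FPKM was 6914 in WT and 213 in rea1, a 32.5-fold difference, and at 18779575 to 18780300 it was 7492 and 782, a 9.58-fold difference. The locus at 18789875 to 18790599 had 148 FPKM in WT and 90.8 in rea1, which is within 2-fold. The sequences of these loci were not examined. If neighbouring loci of such like span share fragments, the values of single loci are uncertain and the sum is the firmer measure.

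The other regions showed sums lower by similar amounts. On chromosome 4, the region from 5098147 to 5159215 had 54236 FPKM in WT and 16165 in rea1, a 3.36-fold difference. In it, 3 rows shared the position 5098147 to 5142076. Of these, 1 had 31839 FPKM in WT and 8543 in rea1, 1 had 4248 and 1434, and the remaining row ran the other way, with 125 FPKM in WT and 359 in rea1. A second region of chromosome 4, from 29963321 to 30091004, had 9693 FPKM in WT and 2540 in rea1, a 3.82-fold difference. On chromosome 1, the region from 161790710 to 162007636 had 14844 FPKM in WT and 5021 in rea1, a 2.96-fold difference. Its end loci differed in size of change, at 1.76-fold lower (161790710 to 161791432) and 5.52-fold lower (162006911 to 162007636). Under the scaling that sets the median ratio of well-expressed loci to 0, the regional differences ranged from 3.47-fold to 4.47-fold, in the same direction.

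**Figure D1:**
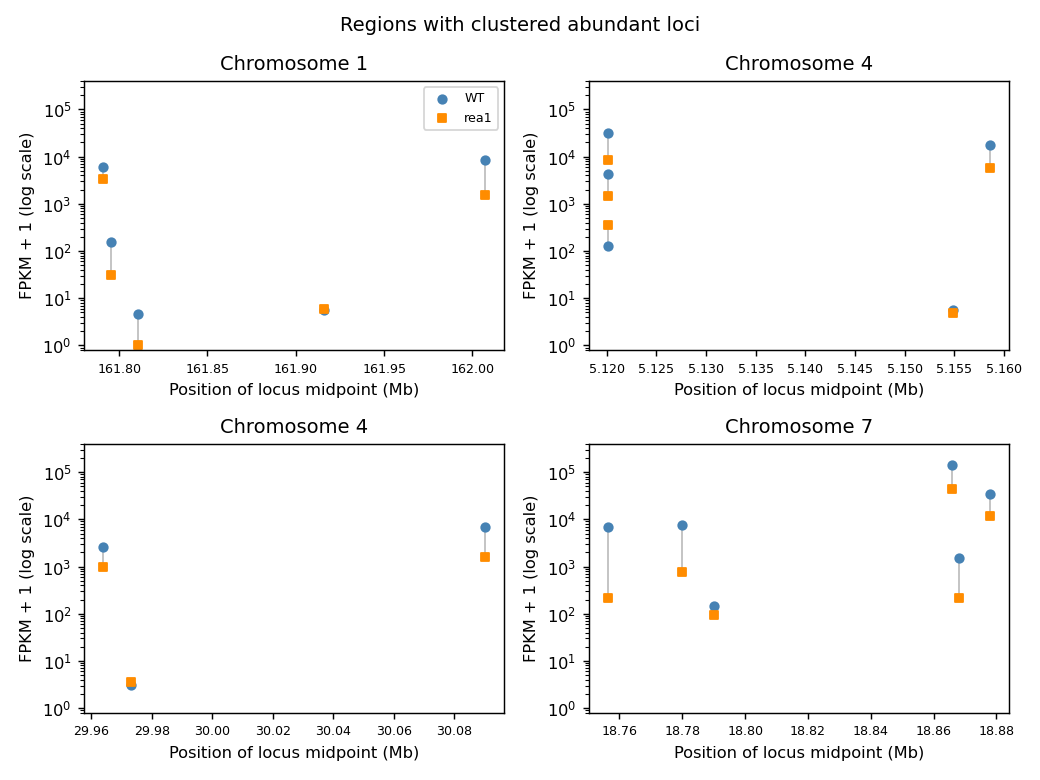
FPKM + 1 (log scale) in WT (circles) and rea1 (squares) against the midpoint of each locus in Mb, for loci reaching 1 FPKM in the 4 regions with clustered abundant loci, with 1 library per genotype. In the chromosome 7 panel all 6 loci lie lower in rea1, and in the first chromosome 4 panel 1 of the 3 rows sharing a position lies higher in rea1.

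Of the 8 loci at a mean of 1000 FPKM or more outside these regions, 5 were lower and 3 higher in rea1, and 1 differed by 2-fold. On chromosome 6, FPKM at 39091667 to 39092487 was 3335 in WT and 1589 in rea1, 2.10-fold lower. Its neighbour at 39087615 to 39088302, which belongs to the next lower expression class, had 1507 FPKM in WT and 73.1 in rea1, 20.6-fold lower. The locus at 24164578 to 24165296 of chromosome 7 had 2722 FPKM in WT and 2392 in rea1, and that at 165423394 to 165426172 had 1734 and 1527. The locus at 23267684 to 23271612 of chromosome 9 had 1554 and 1212, and that at 4676400 to 4679041 of chromosome 10 had 1297 and 1147. Higher values in rea1, within 2-fold, were found at 154814153 to 154815523 of chromosome 9 (2928 FPKM in WT and 3812 in rea1), at 70732363 to 70733351 of chromosome 6 (1479 and 2196) and at 51608197 to 51609614 of chromosome 8 (1100 and 1951).

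Loci of the next lower expression class were mostly higher in rea1. Of 184 loci with a mean of 100 to 1000 FPKM and a span of at least 500 bp, 82 were 2-fold or more higher in rea1, 14 were lower, and 88 lay within 2-fold. The median log2 ratio of the class was 0.85 (95% interval 0.51 to 1.09), and its share of the summed FPKM of loci of this span was 25.9% in rea1 and 9.44% in WT. That sum was 221739 in rea1 and 383609 in WT, so part of the difference in share comes from the smaller rea1 sum. Over all spans, loci at 100 to 1000 FPKM held 13.8% in rea1 and 9.36% in WT. The most abundant of the 82 lay on chromosome 4 at 194518163 to 194520236, with 1395 FPKM in rea1 and 355 in WT, 3.93-fold higher. Others were at 4596812 to 4616642 of chromosome 6, with 1141 FPKM in rea1 and 320 in WT, and at 10483475 to 10486040 of chromosome 2, with 1036 and 306. At lower expression the balance between directions was closer. Of 1875 loci at 10 to 100 FPKM, 217 were higher and 85 lower, with a median of 0.23 (0.19 to 0.27). Of 3062 loci at 1 to 10 FPKM, 259 were higher and 250 lower, with a median of 0.0028 (-0.017 to 0.038). Scaling to a median ratio of 0 among well-expressed loci removed a log2 shift of 0.23 and left medians of 0.62 at 100 to 1000 FPKM and -1.67 at 1000 FPKM or more, while the medians at 10 to 100 and 1 to 10 FPKM became 0.016 and -0.17. The numbers higher and lower then were 129 and 128 at 10 to 100 FPKM, the class this scaling mostly centres, and 195 and 347 at 1 to 10 FPKM, against 68 and 15 at 100 to 1000 FPKM.

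**Figure D2:**
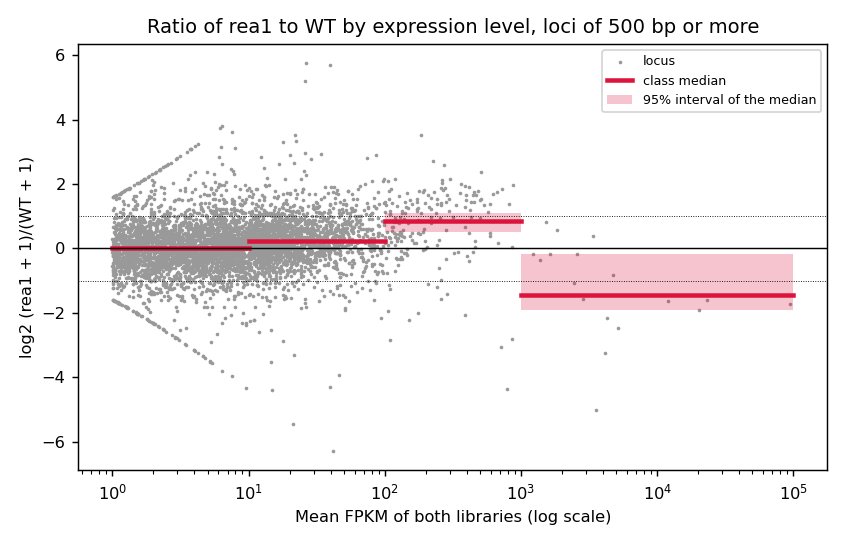
Log2 ratio of rea1 over WT, with a pseudocount of 1, against the mean FPKM of both libraries (log scale) for loci of 500 bp or more. Points are loci, red lines are the medians of 4 expression classes and shading is the 95% interval of each median; the median is 0.85 at 100 to 1000 FPKM and -1.44 at 1000 FPKM or more.

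Over all loci that reached 1 FPKM in either library, 738 of 5995 were 2-fold or more higher in rea1 and 580 were lower, so that 56.0% of the differing loci were higher. With the median ratio of well-expressed loci set to 0, 544 were higher and 754 lower, or 41.9% higher. Scaling by the trimmed mean gave 676 and 625, or 52.0% higher, and a 4-fold threshold on the deposited values gave 127 and 149, or 46.0% higher, so the overall balance of directions depends on both scaling and threshold. Without the 100 most abundant loci, with each library rescaled to its original sum, the numbers were 1203 and 1720, or 41.2% higher. Of the 738 higher loci, 192 were listed at 0 in WT, and of the 580 lower loci, 225 were listed at 0 in rea1. Restricted to loci reaching 10 FPKM with a span of at least 500 bp, where the values rest on more fragments, 351 of 2307 were higher and 146 lower. At 4-fold in this set, 46 were higher and 39 lower. With the median ratio scaled to 0, 230 were higher and 217 lower at 2-fold, a near balance that the scaling itself favours, since it centres nearly the same loci.

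The largest ratios came from very short loci. The highest log2 ratios by the rule fixed in advance were at 19496970 to 19497136 of chromosome 8, a span of 167 bp with 141583 FPKM in rea1 and listed at 0 in WT, and at 79225727 to 79226079 of chromosome 2, a span of 353 bp with 213 FPKM in rea1 and listed at 0 in WT. The lowest were at 144915969 to 144916313 of chromosome 6, a span of 345 bp listed at 0 in rea1 and with 3828 FPKM in WT, and at 153419333 to 153419522 of chromosome 5, a span of 190 bp listed at 0 in rea1 and with 3514 FPKM in WT. Of the 30 largest ratios among loci reaching 10 FPKM, 24 belonged to spans under 500 bp, which made up 6.26% of such loci. Loci under 500 bp held 51% of the summed FPKM in rea1 and 15.9% in WT. The 167 bp locus of chromosome 8 alone made up 31.3% of the rea1 sum, and without it the share of short loci in rea1 was 28.8%. Among loci reaching 1 FPKM, a difference of 4-fold or more was found for 72 of 171 with a span under 300 bp (42.1%, 95% Wilson interval 35.0 to 49.6) and for 20 of 1795 with a span of 5000 bp or more (1.11%, 0.72 to 1.71).

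**Figure D3:**
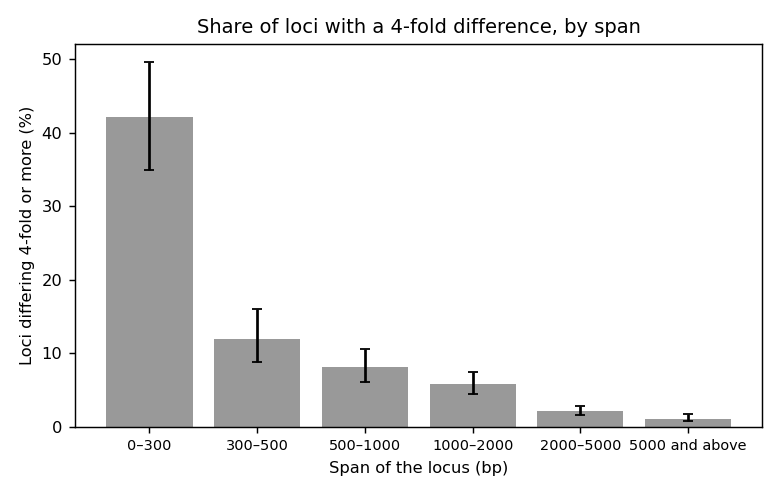
Percentage of loci reaching 1 FPKM that differed by 4-fold or more in either direction between rea1 and WT, by span of the locus in bp. Bars are shares and error bars are 95% Wilson intervals, which cover the number of loci only; the share falls from 42.1% under 300 bp to 1.11% at 5000 bp or more.

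Among longer loci above 0 in both libraries, large differences were found at single positions. The locus at 124589273 to 124591934 of chromosome 4 had 78.3 FPKM in rea1 and 0.52 in WT, and that at 198478457 to 198479148 of chromosome 2 had 51.6 and 0.45. The locus at 85885932 to 85886638 of chromosome 6 was 11.8-fold higher in rea1, at 341 FPKM against 28.9. In the other direction, FPKM at 132250530 to 132252119 of chromosome 8 was 82.8 in WT and 0.082 in rea1, and at 123079301 to 123083985 of chromosome 9 it was 29.0 and 0.44. Apart from the chromosome 6 locus, the lower value of each pair was 0.52 FPKM or less, so the size of the fold is uncertain.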

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

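The expression classes and the restrictions to longer loci, to loci above 0 in both libraries and to summed positions were added after seeing the data. The median log2 ratio at 1000 FPKM or more stayed between -1.67 and -1.26, and that at 100 to 1000 FPKM between 0.32 and 0.85, under the changes of pseudocount and scaling run for each and with positions summed (rescaling without the top 100 loci gives no value at 1000 FPKM or more, and filters on low values remove no locus of these classes and test nothing here), the lowest after removal of the 100 most abundant loci, which takes loci out of this class and removes a log2 shift of 0.27 from every ratio. The median at 1 to 10 FPKM became -0.17 with the median ratio scaled to 0, -0.047 with the trimmed mean and -0.25 without the top 100 loci. With a minimum of 10 FPKM for the higher value, the median was 0.31. That filter keeps only loci of this class with 1 library at 10 FPKM or more and the other below 10 FPKM. Such loci are selected on their difference, so the 0.31 does not describe the class. The numbers of loci higher and lower in rea1 depended on pseudocount, threshold, scaling and filters. They were 211 and 112 with a pseudocount of 10, 389 and 197 with a minimum of 10 FPKM, and 1203 and 1720 after rescaling without the top 100 loci. Thresholds of 1.5-fold and 4-fold gave 1474 and 1097, and 127 and 149. Loci at 10 FPKM and 500 bp or more gave 351 and 146, and loci above 0 in both libraries gave 546 and 355. The rescaling without the top 100 loci raises all remaining values, so more loci pass 1 FPKM. The 10 most abundant loci held 66.6% of the summed FPKM in rea1 and 68.7% in WT, but 38.5% and 70.3% when spans under 500 bp were left out. By the rough fragment numbers above, depth limits ratios near 1 FPKM. No paired analysis was possible because each genotype has 1 library, and no library could be left out. The alternatives built on gene lists or storage protein genes, and those for replicate columns, were not run.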

Other observations

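The tests in this part were chosen after the patterns were seen, and only the prediction for fragments at short loci was set down before its result. Among the 2307 loci of 500 bp or more that reached 10 FPKM, 9 were listed at 0 in one library. The highest in rea1 was at 81861621 to 81862419 of chromosome 10, with 52.5 FPKM in rea1, and the highest in WT was at 61516605 to 61524895 of chromosome 8, with 42.5 FPKM in WT. For spans under 500 bp, 40 of 154 such loci were listed at 0 in one library. At 36 positions, several rows reached 10 FPKM. Rows differed by 2-fold in opposite directions at 1 of these, the chromosome 4 position described above. All rows were 2-fold higher at 2 positions and 2-fold lower at 2. At the remaining positions not every row passed 2-fold, so these counts say little about agreement between rows.

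The opposite shifts at 100 to 1000 FPKM and at 1000 FPKM or more are the pattern most open to follow-up. A single scaling difference between libraries, such as the share freed when abundant transcripts fall, would move every class alike, and the tables argue against it as the whole cause: the median at 100 to 1000 FPKM exceeded that at 1 to 10 FPKM by 0.85 on the log2 scale, with intervals that do not overlap. Length correction at loci of short span is argued against for the middle class. Its median was 1.13 at 2000 to 5000 bp and 0.43 (95% interval 0.32 to 0.58) at 5000 bp or more, against 0.66 at 500 to 2000 bp. Span includes introns, so an effect of short transcripts in long loci cannot be excluded. Reassignment of fragments between copies inside the 4 regions is argued against for the abundant loci, since the summed FPKM of every region was at least 2.96-fold lower in rea1. A sum of FPKM stays the same under reassignment only between transcripts of like length. The chromosome 7 loci that reached 1 FPKM were of like span. The first chromosome 4 region joined spans of 43930 and 1317 bp, so the argument is weaker there. The sums cannot show whether fragments were assigned to like copies outside the regions, or to unlisted copies inside them, which was not tested. The genotype, a difference in developmental stage between the kernels sampled and variation between single libraries also stay open. With 1 library per genotype they cannot be told apart.

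The 4-fold differences at short spans may reflect few fragments combined with the correction for transcript length. If so, short loci with more fragments should differ less often. Among loci of 200 to 300 bp, 8 of 23 whose higher value stood for about 20 or more fragments differed by 4-fold (34.8%, 95% Wilson interval 18.8 to 55.1), against 47 of 116 with fewer (40.5%, 32.0 to 49.6). The intervals overlap, so the explanation stays open at this number of loci. The split concerns fragment number only and does not test the length correction. At 200 to 300 bp the lowest 2% of values above 0 lay below 0.341 FPKM times kilobases in rea1 and 0.580 in WT. At 1000 to 3000 bp these limits were 0.0866 and 0.108. If such values stand for 1 fragment, a fragment carried more FPKM times kilobases at the short spans. No biological explanation was tested for the 4-fold differences.

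Chromosome 6 had the highest share of loci with a 2-fold difference. Of its 408 loci of 500 bp or more reaching 1 FPKM, 103 differed (25.2%, 95% Wilson interval 21.3 to 29.7), against 16.4% to 20.3% on the other 9 chromosomes and 18.2% over their 5105 loci together. The expression level and span of its loci, as far as they were matched, are argued against as the whole cause. The share lay at percentile 99.8 of 10000 random lists matched on 20 bins of mean FPKM and 3 classes of span. This was the highest of 10 chromosomes compared, and the lists treat neighbouring loci as independent, so the percentile may overstate the excess. A hypothesis is that part of chromosome 6 differs in parental background between mutant and WT, and then the excess could sit in a single block. Leaving out any one of 33 overlapping 30 Mb blocks left between 23.9% and 26.3%, above the pooled share of the other chromosomes. The central 95% of matched random lists for chromosome 6 lay between 16.4% and 23.5%, however, and the share left fell to percentile 96.0 of such lists without 130000001 to 160000000. A single block therefore cannot be told apart from a wider spread at this number of loci. Chromosome 6 stayed highest at a minimum of 10 FPKM (31.3% against at most 26.6%), but its lead was small with a pseudocount of 10 (6.86% against 6.38%) and at 4-fold (4.66% against 4.64%).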
